A study of Mus musculus with 8 samples.

How the data were processed

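RNA was sequenced from mouse embryonic fibroblasts (MEFs), connective tissue cells grown out of mouse embryos and used here at passages 3 to 5 on a C57BL/6 background, per the labels. The 8 libraries fall into 4 groups of 2: wild-type (WT) cells and cells labelled as knockouts of Kdm3a, a histone H3K9 demethylase gene, each fed (0 h) or kept for 12 h without glucose. Fed cells grew in DMEM with 10% serum, and starved cells were moved to glucose-free DMEM with 10% dialyzed serum, per the labels' protocols. No group was kept fed for 12 h or given dialyzed serum with glucose. Loss of glucose therefore cannot be separated from the change of medium, the dialyzed serum and the 12 h of time, and starvation below means all of these together. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical.

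The authors deposited whole-number read counts per RefSeq transcript, not normalised, in 1 table of 31055 rows for 23366 gene symbols. The submitters' processing notes name TopHat2 2.0.9, bedtools and the mouse genome build mm9, without roles or parameters. Whether the library kit kept strand, how reads with several matches were counted and which reads were filtered out are not given in the sources used here. No row named no gene. A further 4 columns of per-sample values matched no sample in the labels and were not used. A reference annotation of another build (GRCm38) served only for chromosome names and for which genes neighbour each other, so no coordinates are given.

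Of the symbols, 4447 had more than 1 row. Among 4592 isoform rows of symbols whose top row held at least 1000 counts, 78.6% held at least 90% of the count of the top row, so rows of one gene repeat the same reads and were not added up. Each symbol was represented by its row with the highest total over the 8 libraries. Totals on this basis ran from 38407526 to 53602297 counts per library, and 14426 to 16050 genes had a count. Genes with near-identical copies (ribosomal protein genes, Raet1d, Oas1a and Serpina3g) are uncertain because the counting may split reads among copies, and Xist and its antisense partner Tsix cannot be told apart without strand.

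Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter (14418 genes kept), 1 coefficient per group over all 8 libraries (4 residual degrees of freedom), the quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 5 comparisons were starved against fed in WT, starved against fed in KO-labelled cells, KO-labelled against WT when fed and when starved, and the difference between the 2 starvation responses, called the interaction. Fold changes are on the log2 scale with a standard error. It was computed as the absolute log2 fold change over the square root of the F statistic. It is thus derived from the test and is not a separate estimate. Levels in CPM are counts scaled by the TMM-adjusted library total and are given as mean ± SD of 2 libraries. The common biological coefficient of variation was 0.0341. Against a group with 0 counts, a fold is a lower bound computed with 3 counts per library in that group; against a group with 1 to 6 counts over its 2 libraries it is a ratio with a 95% Clopper-Pearson interval. Intervals and floors cover counting error only. The floor of 3 counts corresponded to 0.0706 CPM in fed WT, 0.0915 in starved WT, 0.0541 in fed KO-labelled and 0.0616 in starved KO-labelled libraries.

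Gene lists, the test, the rule for named genes and most alternatives were fixed before the data were examined. The 28 tested lists held autophagy machinery, lysosome, ATF4 amino acid and stress response, ER chaperones and unfolded protein response, glycolysis, hypoxia response, sterol and fatty acid synthesis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, DNA replication and G1/S, mitosis and G2/M, p53 targets, NRF2 targets, immediate-early genes, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, collagens and extracellular matrix, smooth muscle and contractile genes, H3K9 demethylases and methyltransferases, Hox genes, and markers of macrophages and blood cells, endothelium, epithelium, skeletal muscle, cartilage and bone, neural and glial cells, and adipocytes. Of 959 symbols in the lists, 957 were in the table. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, and adjusted over 140 tests. The test was repeated with an estimated correlation. In WT starvation the estimate was 0.624 for ribosomal proteins but -0.001 for autophagy and -0.032 for hypoxia genes, below the preset 0.01. Where the estimate lies below the preset value, a larger adjusted p in the repeated test is not owed to a stronger correlation. For the ATF4 list in WT starvation the estimate was 0.013, near the preset value. Its camera adjusted p still went from 1.05e-53 to 0.00414. A larger adjusted p in the repeated test alone therefore does not show that the genes of a list are correlated.

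The rule for named genes took Kdm3a; per pairwise comparison the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM and library ranges that did not overlap; the 5 most positive and 5 most negative interaction genes; up to 4 called members per list and comparison with the smallest adjusted p; Txnip, Arrdc4, Becn1, Ulk1, Tfeb, Map1lc3b and Sqstm1 whatever their p; and 5 sex-linked genes. The text gives part of the genes this rule named, and some are not reported here. Genes outside it are said to have been chosen after their values were seen.

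The alternatives were RLE size factors, no low-count filter, a minimum mean of 5 CPM, DESeq2 1.42.0, limma voom, a replicate block, a fit of the 4 libraries of a comparison alone, each library left out in turn and, for the ratio of responses, other prior counts. Scaling by library totals without TMM factors, the sum of isoform rows and the removal of X- and Y-linked genes were chosen after seeing the data. The response ratio was the slope of the response in KO-labelled cells on that in WT, from a regression through the origin over genes of log2 CPM (prior count 2). It was weighted by 1 pair of WT libraries and measured in the other pair, for 4 splits. Tables were joined in Python 3.11.15.

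The tests were checked on simulated counts drawn from the means and totals of these libraries. Of genes changed by 1.5-fold, the test recovered 59.2% in the WT starvation comparison, 79.2% in the KO-labelled one, 83.7% and 81.6% in the fed and starved comparisons of KO-labelled with WT, and 75% in the interaction; at 1.1-fold it recovered 8.2%, 16.3%, 16.7%, 14.6% and 4%. Between 0.04% and 0.08% of unchanged genes were called. Most simulated genes were unchanged, 13746 of 13941 in the WT starvation comparison, whereas 81.6% of genes were called there in the data. The Benjamini-Hochberg adjustment depends on the share of changed genes, so these recovered and called shares do not carry over to the data. The list test called the autophagy list simulated at 1.5-fold in the WT starvation comparison and none of 54 unchanged list tests, and the response ratio simulated at 0.6 was recovered as 0.6. Simulated genes varied independently, and the simulated KO-labelled response was an exact multiple of that of WT. These checks therefore say nothing about lists of correlated genes or about responses that agree only in part.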

Results

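The data set held RNA sequencing counts from 8 libraries of mouse embryonic fibroblasts, 2 in each of 4 groups: WT fed, WT starved of glucose for 12 h, KO-labelled fed and KO-labelled starved. The design asked how gene expression differs between WT and Kdm3a knockout cells with nutrients and without glucose, in a study of the control of autophagy by this histone demethylase. With 1 row per gene, the fed WT libraries held 39781784 and 38407526 counts, the starved WT libraries 41019748 and 41775284, the fed KO-labelled libraries 52443086 and 42697301 and the starved KO-labelled libraries 45792465 and 53602297. The 10 genes with the most counts took 4.66 to 5.78% of counts in fed and 6.7 to 8.96% in starved libraries, led by Eef1a1, a translation elongation factor gene, in each library. Replicates correlated at r = 0.9911 to 0.9948 across genes and libraries of different groups at 0.8402 to 0.9192. Genes are not independent replicates. Replicate counts differed by more than sampling noise in each group (chi-square per degree of freedom 3.37 to 6.21). Levels are mean ± SD in CPM (n = 2 libraries) and log2 fold changes are given ± SE. Calls are those of edgeR's quasi-likelihood test at an adjusted p under 0.05. Counts of list members that passed were the same when adjusted over the list alone, except where a second count is given.

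Kdm3a, the targeted gene (row NM_173001), was read at 56.1 and 56.4 CPM in the fed WT libraries and at 55.2 and 55.4 CPM in the fed libraries labelled KO. The difference was -0.02 ± 0.043 (adjusted p = 0.619), and the lowest Kdm3a count in a KO-labelled library was 2788. After starvation it reached 176 and 185 CPM in WT and 65.4 and 66.7 CPM in the libraries labelled KO, a difference of -1.45 ± 0.041. Counts per whole transcript cannot show the loss of an exon, so the fed values check nothing about such an allele. As the fed values do not show the loss that the label names, these libraries are called KO-labelled throughout and every direction below rests on that label. The sex-linked genes also separated the genotypes. Xist, the RNA of the inactive X chromosome, stood at 0.939 to 1.54 CPM in the WT libraries and 869 to 1370 CPM in the KO-labelled libraries, where its reads could include those of Tsix. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 296 to 1251 counts in each WT library and 0 to 2 counts in each KO-labelled library. In fed cells Ddx3y was at least 511-fold, Eif2s3y at least 426-fold, Kdm5d at least 368-fold and Uty at least 229-fold lower in the libraries labelled KO. Genotype and sex of the cells therefore could not be separated in any comparison between the labels.

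**Figure D1:**
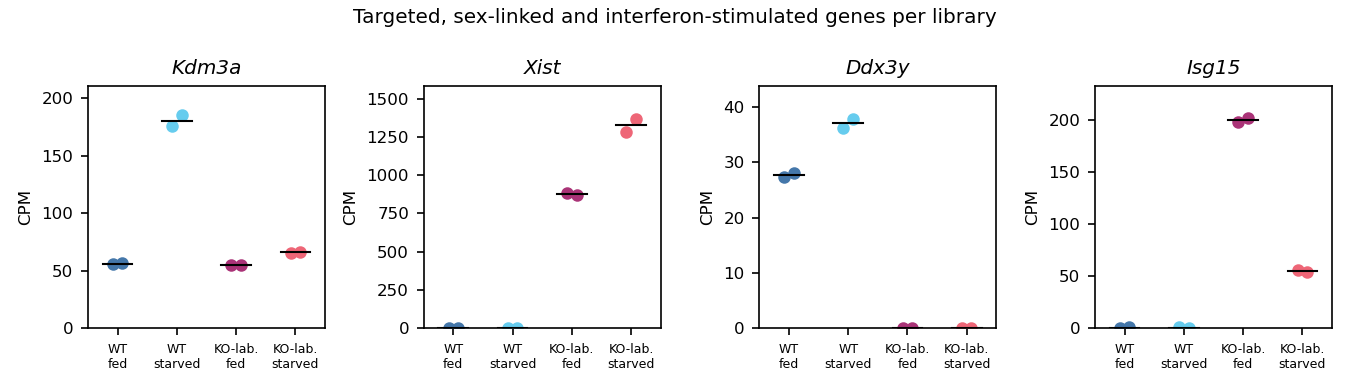
Levels of Kdm3a, Xist, Ddx3y and Isg15 in CPM (vertical axis, from 0) in each library (points) of the 4 groups, with the group mean as a line. Kdm3a lies between 55.2 and 56.4 CPM in the 4 fed libraries, while Xist and the interferon-stimulated gene Isg15 are high in the libraries labelled KO and Ddx3y in the WT libraries.

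The first comparison asked what differed in WT cells after 12 h without glucose, with the changed medium, serum and time that came with it. Genes of the ATF4 amino acid and stress response and of the ER chaperones rose, and genes of mitosis fell. Ddit3, which encodes the stress transcription factor CHOP, rose from 27.3 ± 1.1 to 1010 ± 8.8 CPM (log2 fold change 5.2 ± 0.037). Hspa5, the ER chaperone BiP, rose from 561 ± 0.45 to 5590 ± 5.8 CPM (3.32 ± 0.023). Col1a1, a chain of the main fibrillar collagen, fell from 4660 ± 130 to 247 ± 10 CPM (-4.24 ± 0.032), and Txnip, an arrestin-like gene that responds to glucose, fell from 47.8 ± 5.8 to 0.35 ± 0.15 CPM (-7.08 ± 0.17). Of 14418 genes tested, 5296 rose and 6465 fell, 2164 and 3952 of them by more than 2-fold. Scaled by library totals, 3397 rose and 8629 fell, the median of all genes moved by -0.46, and 744 calls turned direction, so changes are relative to TMM scaling. The share of higher calls was 45% with TMM and 28.2% with library totals.

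In the ATF4 list 47 of 50 tested members rose and 3 fell in WT (camera adjusted p = 1.05e-53; adjusted p = 0.00414 with an estimated correlation). They included Ppp1r15a, the stress-induced phosphatase subunit GADD34 (5.07 ± 0.041), Chac1, a glutathione-degrading enzyme (4.81 ± 0.051), and Slc3a2, the heavy chain of amino acid transporters (3.68 ± 0.03). Of 41 ER chaperone and unfolded protein response genes 33 rose and 6 fell (7 adjusted over the list alone; camera adjusted p = 1.88e-19, and 0.0118 as the adjusted p with an estimated correlation). Herpud1, of ER-associated degradation, rose 9.17-fold and Hyou1, an ER chaperone, 6.71-fold. The stress gene Atf3 went from 3.36 ± 0.25 to 204 ± 7.2 CPM and Gadd45a, a growth arrest gene, from 10 ± 0.95 to 508 ± 4.9 CPM. Among the largest rises were also Fam110c (129-fold) and Car6, a secreted carbonic anhydrase (45.2-fold). Hmox1, heme oxygenase, rose 20.3-fold and Gclc, of glutathione synthesis, 6.39-fold, but the NRF2 target list, with 14 of 27 higher and 8 lower, had a median of 0.26 that turned to -0.19 with library totals. Its camera adjusted p of 0.0148 was 0.0763 with library totals and 0.211 as the adjusted p with an estimated correlation.

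Autophagy genes moved up on balance in WT: 34 of 53 rose and 11 fell, with a median of 0.47 that shrank to 0.02 with library totals, where 24 rose and 24 fell. The camera adjusted p was 0.00104, and the adjusted p = 0.0669 with an estimated correlation. Sqstm1, an autophagy receptor, rose from 392 ± 3.3 to 1770 ± 9.1 CPM, Fam134b, a receptor for ER autophagy, from 15.8 ± 0.38 to 143 ± 2.5 CPM, and Atg14, a subunit of the autophagy lipid kinase complex, from 14.4 ± 0.23 to 126 ± 2.2 CPM. Map1lc3b (LC3B) rose by 0.85 ± 0.032, Becn1 by 0.91 ± 0.039 and Atg3 by 1.48 ± 0.047. Tfeb, a transcription factor of lysosomal genes, fell by 1.34 ± 0.1 on the log2 scale, and Ulk1, the initiating kinase, differed by -0.09 ± 0.051 (adjusted p = 0.119). With library totals Ulk1 was called lower (-0.54), and likewise with a minimum of 5 CPM (-0.15). In the lysosome list 36 of 53 rose and 16 fell (median 1.05, and 0.59 with library totals; camera adjusted p = 4.24e-09, and 0.0184 as the adjusted p with an estimated correlation), among them Atp6v1c1, a proton pump subunit (2.82 ± 0.037), Ctsa, a protease (2.1 ± 0.029), and Lamp1, a membrane protein (1.65 ± 0.028).

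**Figure D2:**
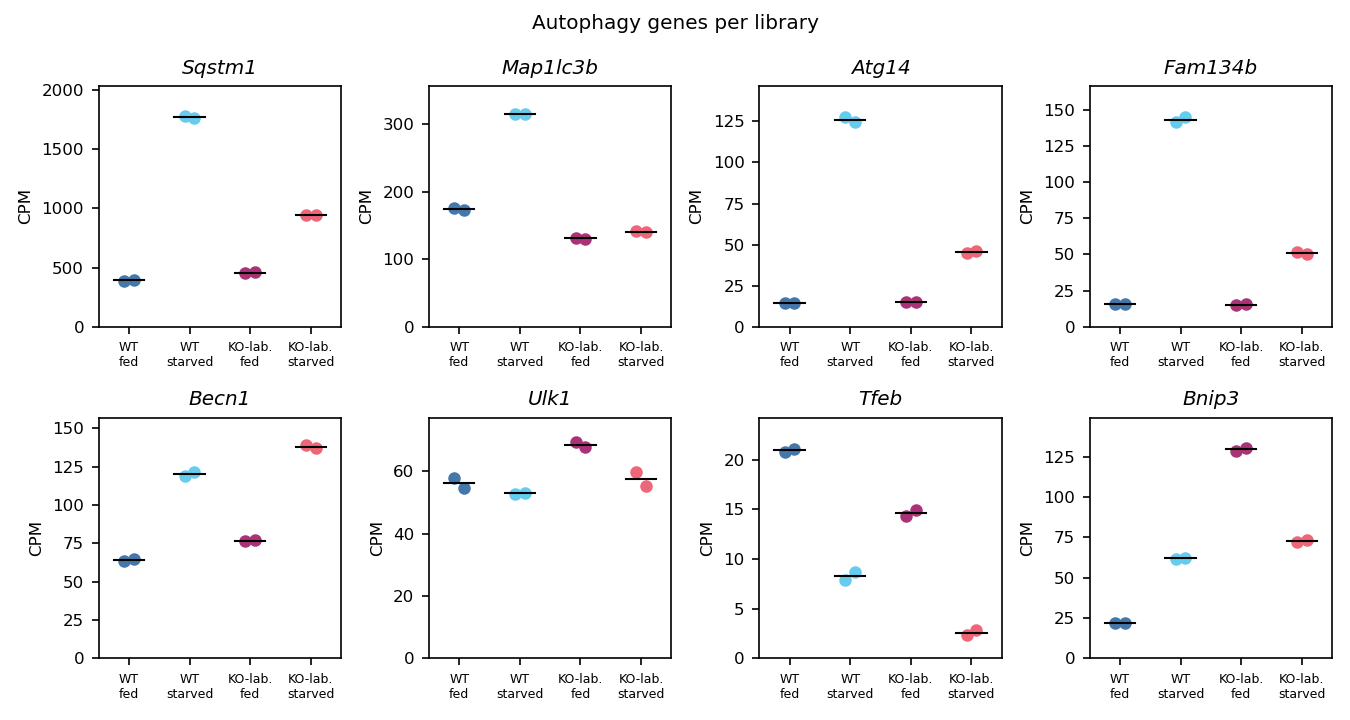
Levels of Sqstm1, Map1lc3b, Atg14, Fam134b, Becn1, Ulk1, Tfeb and Bnip3 in CPM (vertical axis, from 0) in each library (points) of the 4 groups, with the group mean as a line. Sqstm1 goes from 392 to 1770 CPM in WT and from 457 to 946 CPM in KO-labelled cells, and Map1lc3b from 175 to 315 CPM and from 131 to 141 CPM; the small rise of Map1lc3b in KO-labelled cells turns to a fall with library totals.

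Among the genes that fell in WT, 42 of 45 mitosis and G2/M genes were lower and 3 higher (median -1.6; camera adjusted p = 2.01e-23, and 0.00743 as the adjusted p with an estimated correlation). The proliferation marker Mki67 fell from 379 ± 10 to 50.9 ± 2.7 CPM and Top2a, a topoisomerase of dividing cells, from 434 ± 0.15 to 120 ± 0.25 CPM. Of 47 DNA replication genes 29 fell, among them Tk1, thymidine kinase (-3.62 ± 0.055), and 10 rose, among them Mcm2, a helicase subunit (1.32 ± 0.029). The camera adjusted p was 0.0174, and the adjusted p = 0.271 with an estimated correlation. In the sterol and fatty acid synthesis list 27 of 34 fell and 4 rose (camera adjusted p = 5.11e-07, and adjusted p = 0.0798 with an estimated correlation), with Scd2, a desaturase, down 19.3-fold. Of 43 collagen and matrix genes 25 fell and 14 rose (median -0.91, or -0.78 with genes at 0 counts set to their bound and -1.37 with library totals; camera adjusted p = 1.46e-07, and adjusted p = 0.303 with an estimated correlation). Col3a1 fell 21.9-fold. Of 29 cytokine and NF-kB genes 19 fell and 4 rose (camera adjusted p = 1.32e-05, and 0.0463 as the adjusted p with an estimated correlation): Cxcl5, a chemokine, went from 1360 ± 13 to 23.8 ± 0.45 CPM, while Ptgs2, cyclooxygenase 2, went from 32.5 ± 0.063 to 878 ± 8.6 CPM. Steap4, a metalloreductase, had 331 counts in fed and 0 in starved WT libraries, at least a 42.7-fold fall, and Adamts4, a matrix protease, had a ratio of 237 (95% interval 65.2 to 1960). Gas1, a growth arrest gene, fell 76.7-fold and Cd248, a stromal marker, 201-fold.

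Of the remaining lists in WT, all 75 ribosomal protein genes rose (median 1.01, and 0.55 with library totals; camera adjusted p = 2.66e-26), but the adjusted p was 0.26 with an estimated correlation. In the hypoxia list 13 of 27 rose and 11 fell, with a median of 0.18 that turned to -0.28 with library totals (camera adjusted p = 0.0191, and adjusted p = 0.143 with an estimated correlation). Ndrg1, a stress and hypoxia gene, rose 20.6-fold, Ero1l, an ER oxidase, 10.2-fold and Vegfa, the angiogenic factor, 8.11-fold. Of 26 immediate-early genes 15 rose and 7 fell (median 0.38, turning to -0.08 with library totals; camera adjusted p = 0.0217, and adjusted p = 0.144 with an estimated correlation). Of 20 contractile genes 12 rose and 6 fell (median 0.5, and 0.05 with library totals; camera adjusted p = 0.00673, and adjusted p = 0.137 with an estimated correlation), among them Tagln (4.92-fold higher) and Tpm1 (2.16-fold lower). Hox genes fell, 29 of 36 with 1 higher (camera adjusted p = 0.0115, but 0.0915 with library totals, and adjusted p = 0.124 with an estimated correlation). The glycolysis list did not pass (camera adjusted p = 0.488; median 0.01, mean -0.27, median -0.44 with library totals), though Hk2, hexokinase 2, rose 3.78-fold and Ldhb, a lactate dehydrogenase subunit, fell 10.1-fold. Kdm4b, Jmjd1c and Kdm4c, H3K9 demethylase family genes, rose by 1.6 ± 0.055, 1.21 ± 0.043 and 1.5 ± 0.06, while their list had 11 higher and 7 lower of 18 and did not pass (camera adjusted p = 0.32; median 0.35, mean -0.13, median -0.11 with library totals). Fatty acid oxidation (camera adjusted p = 0.258) and oxidative phosphorylation genes (camera adjusted p = 0.245; median 0.27, turning to -0.18 with library totals) did not pass either, although Acadm, of medium-chain fatty acid oxidation, fell 6.21-fold.

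In KO-labelled cells, the comparison asked what the same starvation changed. ATF4 and ER chaperone genes rose and mitosis genes fell here too, and interferon-stimulated genes fell. Ddit3 rose from 17.7 ± 0.47 to 788 ± 5.4 CPM and Hspa5 from 733 ± 0.023 to 6710 ± 19 CPM. Mitotic kinase gene Plk1 fell from 165 ± 2.6 to 12 ± 1.3 CPM and Txnip from 59.5 ± 1.2 to 0.623 ± 0.19 CPM. In all, 5678 genes rose and 5812 fell, 1897 and 2888 of them by more than 2-fold. With library totals 4261 rose and 7242 fell (49.4% of calls higher with TMM, 37% with totals, a median shift of -0.26, and 171 calls turned).

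The ATF4 list had 47 of 50 members higher and 2 lower in KO-labelled cells (median 2.36; camera adjusted p = 2.83e-77, and 0.00414 as the adjusted p with an estimated correlation), and the ER list 39 of 41 higher and 2 lower (median 1.94; camera adjusted p = 5.42e-59, and 0.00414 as the adjusted p with an estimated correlation). Slc3a2 rose 19.8-fold, Creld2, an ER stress gene, 15.1-fold, Hyou1 13.1-fold and Pdia4, a disulfide isomerase, 7.86-fold. Among autophagy genes 30 of 53 rose and 17 fell (18 adjusted over the list alone), with a median of 0.17 that turned to -0.09 with library totals. The list did not pass (camera adjusted p = 0.0528, and 0.204 with an estimated correlation), but it passed at 0.0491 without starved KO-labelled replicate 1 and with summed isoforms. Sqstm1 rose 2.07-fold, Fam134b 3.33-fold, Atg14 3.02-fold, Atg13, of the initiating kinase complex, 3.47-fold and Becn1 by 0.85 ± 0.037. Tfeb fell 5.66-fold and Ulk1 fell by 0.25 ± 0.047 on the log2 scale. Map1lc3b was called higher by 0.11 ± 0.032 (adjusted p = 0.00448), a call that ended with DESeq2 (0.07), with a minimum of 5 CPM (0) and without starved WT replicate 1 or replicate 2 (0.05 each), and that became a fall of -0.15 with library totals. Kdm3a rose by 0.26 ± 0.042, and by 0 with library totals (adjusted p = 0.976). Lysosome genes rose, 42 of 53 with 8 lower (median 0.7, and 0.44 with library totals; camera adjusted p = 1.69e-08, but adjusted p = 0.0527 with an estimated correlation), for example Neu1, a sialidase (4.28-fold), Mcoln1, a calcium channel (4.18-fold) and Atp6v1b2, a proton pump subunit (4.94-fold).

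All 45 mitosis genes fell in KO-labelled cells (median -2.13; camera adjusted p = 8.08e-54, and 0.0103 as the adjusted p with an estimated correlation). Of 43 interferon-stimulated genes 42 fell (median -2.71; camera adjusted p = 1.04e-38, and 0.0103 as the adjusted p with an estimated correlation), such as Samd9l, an antiviral gene (15.3-fold), and Cmpk2, a nucleotide kinase (from 20 ± 1.8 to 0.284 ± 0.026 CPM). In WT, where the levels were low, 23 of these 43 fell (22 adjusted over the list alone) and 4 rose without the list passing (camera adjusted p = 0.136; median -1.23, or -0.86 with genes at 0 counts set to their bound). Of 29 cytokine and NF-kB genes 18 fell and 8 rose (camera adjusted p = 1.91e-05, and 0.0473 as the adjusted p with an estimated correlation), with Cxcl12, a chemokine of stromal cells, down 13.2-fold and Ptgs2 up 6.31-fold. Sterol genes fell, 25 of 34 with 6 higher (camera adjusted p = 1.66e-05, but adjusted p = 0.143 with an estimated correlation), as did 27 of 43 collagen and matrix genes with 12 higher (camera adjusted p = 0.000508, but adjusted p = 0.486 with an estimated correlation) and 31 of 47 replication genes with 8 higher (camera adjusted p = 0.00582, but adjusted p = 0.239 with an estimated correlation). Col1a2 fell 7.28-fold and Tk1 5.92-fold. Contractile genes rose, 16 of 20 with 2 lower (median 1.04; camera adjusted p = 7.26e-12, and 0.0463 as the adjusted p with an estimated correlation): Acta2, smooth muscle actin, went from 78.4 ± 0.11 to 332 ± 3.1 CPM and Tagln from 41.1 ± 0.61 to 409 ± 6.6 CPM. The 75 ribosomal protein genes all rose (median 0.78; camera adjusted p = 8.54e-20, but adjusted p = 0.321 with an estimated correlation), and 16 of 36 Hox genes fell with 3 higher (camera adjusted p = 0.0373, but 0.197 with library totals and adjusted p = 0.165 with an estimated correlation). Glycolysis genes did not pass (15 of 25 lower, 8 higher; camera adjusted p = 0.106, but 0.0252 with library totals), although Ldha, the main lactate dehydrogenase subunit, fell from 1620 ± 6.9 to 748 ± 4.6 CPM and Slc16a3, a lactate transporter, from 99.8 ± 3.7 to 13.7 ± 0.5 CPM. The hypoxia list did not pass either (camera adjusted p = 0.505; median 0.05, mean -0.15, median -0.21 with library totals). Of the largest changes, Sspo, a secreted glycoprotein gene with 4 counts in fed cells, rose by a ratio of 567 (95% interval 221 to 2080), Slc7a3, an arginine transporter, rose 73.9-fold and Adm2, a peptide hormone gene, 54-fold, while Angpt1, an angiopoietin, fell 103-fold and Iigp1, an interferon-inducible GTPase, 95.3-fold.

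Fed KO-labelled cells were then compared with fed WT cells, which asks what the knockout changes with nutrients present. Interferon-stimulated genes were higher in the libraries labelled KO, and contractile genes were lower. Isg15, an interferon-induced ubiquitin-like gene, was read at 0.697 ± 0.2 CPM in WT and 200 ± 2 CPM in KO-labelled cells, and Bst2, tetherin, at 5.39 ± 0.0083 and 382 ± 10 CPM. Acta2 was 28-fold lower (2200 ± 5 and 78.4 ± 0.11 CPM). Hoxd13, a homeobox gene of distal limb and posterior body, was 992-fold higher (0.271 ± 0.01 and 271 ± 0.014 CPM), while Hoxb9 was 1180-fold lower (76.9 ± 2.1 and 0.0659 ± 0.047 CPM). The size of the fold for Hoxb9 is uncertain, because its level in KO-labelled libraries was near their floor of 0.0541 CPM. In all, 4980 genes were higher and 5742 lower, 1796 and 1621 of them by more than 2-fold. With library totals the median of all genes moved by 0.11, 5811 were higher and 4737 lower, and no call turned.

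Each of the 43 interferon-stimulated genes was higher in fed KO-labelled cells (median 6.4, and 6.52 with library totals; camera adjusted p = 6.74e-118, and 0.00335 as the adjusted p with an estimated correlation). Cmpk2 had 0 counts in fed WT and was at least 283-fold higher. Oas2, an antiviral synthetase gene, had a ratio of 1600 (95% interval 549 to 7780) and Sp100, a nuclear body gene, of 1360 (377 to 11300). For Oas1a, with reads that its copies may share, it was 2030 (868 to 6240), and for Psmb8, an immunoproteasome subunit, 1560 (608 to 5720). Of 28 p53 targets 20 were higher and 6 lower (median 0.77; camera adjusted p = 0.000151, but adjusted p = 0.0926 with an estimated correlation): Cdkn1a, the cell cycle inhibitor, was 5.04-fold higher and Btg2, an antiproliferative gene, 5.72-fold, while Cdkn2a, a locus of other cell cycle inhibitors, was 4.22-fold lower. Of 20 contractile genes 15 were lower and 3 higher (median -1.18; camera adjusted p = 4e-22, and 0.0266 as the adjusted p with an estimated correlation), with Cnn1, calponin, 65.7-fold lower. Of 43 collagen and matrix genes 22 were lower and 18 higher (camera adjusted p = 0.00192, but adjusted p = 0.512 with an estimated correlation), with Postn, periostin, 65.6-fold, Col1a2 23.1-fold and Thy1, a fibroblast surface marker, 16.2-fold lower. Hox genes had 24 of 36 members lower and 7 higher (median -3.33, or -3.13 with genes at 0 counts set to their bound; camera adjusted p = 0.00216, but adjusted p = 0.0965 with an estimated correlation). Hoxc6, at least 320-fold, and Hoxc11, at least 210-fold, were lower, and Hoxd11 was 65.8-fold higher. The transcription factor genes Nkx3-2, Tfap2a and Gata4 had 0 counts in fed WT and were at least 404-fold, 192-fold and 190-fold higher, while Mab21l2, Ldb2 and the imprinted RNA Meg3 had 0 counts in fed KO-labelled libraries and were at least 756-fold, 343-fold and 265-fold lower.

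Autophagy genes were higher on balance in fed KO-labelled cells, 27 of 53 with 9 lower (median 0.17, and 0.28 with library totals; camera adjusted p = 0.037, but adjusted p = 0.143 with an estimated correlation). Bnip3, a mitophagy receptor, was 5.9-fold, Optn, an autophagy receptor, 3.59-fold and Uvrag, of the autophagy lipid kinase complex, 2.24-fold higher. Map1lc3b was lower (-0.42 ± 0.032), as was Tfeb (-0.52 ± 0.091), and Sqstm1 (0.22 ± 0.025), Becn1 (0.26 ± 0.039) and Ulk1 (0.29 ± 0.048) were slightly higher. Lysosome genes were higher in 32 of 53 cases and lower in 15 (camera adjusted p = 0.00578, but adjusted p = 0.0926 with an estimated correlation), for example Ctsz, Npc2 and Ctsl (4.11-fold, 3.53-fold and 2.93-fold). Of 25 glycolysis genes 17 were higher and 8 lower (camera adjusted p = 0.00696, but adjusted p = 0.249 with an estimated correlation). Aldoa was 2.76-fold and Ldha 2.63-fold higher and Ldhb 66.6-fold lower. Txnip was slightly higher (0.32 ± 0.074) and its relative Arrdc4 was 46.3-fold higher. The ER chaperone list, with 29 of 41 higher and 10 lower, did not pass (camera adjusted p = 0.0655, and adjusted p = 0.252 with an estimated correlation). It passed with RLE (0.0479) and with library totals (0.023). Lower lists were ribosomal proteins (59 of 75 lower, 12 higher; camera adjusted p = 1.37e-12, but adjusted p = 0.456 with an estimated correlation), the ATF4 response (33 of 50 lower, 14 higher; camera adjusted p = 0.00673, but adjusted p = 0.0965 with an estimated correlation) and oxidative phosphorylation (39 of 58 lower, 10 higher; camera adjusted p = 0.0428, but 0.0615 with RLE, 0.117 with library totals and adjusted p = 0.675 with an estimated correlation). Aldh18a1, of proline synthesis, was 2.51-fold lower and Atf3 6.38-fold higher. Calls covered 74.2% of 13883 autosomal genes, 78.8% of 471 X-linked genes (85 higher and 286 lower, median -0.38) and each of 4 Y-linked genes. Of the 40 tested genes nearest to Kdm3a 80% were called, against 74.2% of genes on other chromosomes (Fisher's exact test, two-sided p = 0.473).

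After starvation, KO-labelled and WT cells were compared again, which asks what the knockout changes without glucose. ER chaperones, p53 targets and interferon-stimulated genes were higher in the libraries labelled KO. Creld2 was read at 284 ± 3.5 CPM in WT and 995 ± 2.1 CPM in KO-labelled cells, Cdkn1a at 73.9 ± 0.96 and 322 ± 5.6 CPM, and Isg15 at 0.702 ± 0.14 and 54.8 ± 0.9 CPM. Kdm3a was 2.73-fold, Sqstm1 1.87-fold and Tagln 6.91-fold lower. In all, 6036 genes were higher and 5435 lower, 3145 and 1799 of them by more than 2-fold. With library totals 7817 were higher and 3778 lower (52.6% of calls higher with TMM, 67.4% with totals, a median shift of 0.32, and 401 calls turned).

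Of 41 ER genes 39 were higher and 1 lower in starved KO-labelled cells (median 0.93; camera adjusted p = 3.06e-17, and 0.0103 as the adjusted p with an estimated correlation): Sel1l, of ER-associated degradation, was 2.98-fold and Pdia4 2.8-fold higher, while Herpud1 was 2.82-fold lower. Of 28 p53 targets 21 were higher and 5 lower (median 1.24; camera adjusted p = 3.16e-07, and 0.0333 as the adjusted p with an estimated correlation), with Btg2 21-fold and Phlda3, a growth inhibitor, 8.32-fold higher. All 43 interferon-stimulated genes were higher (median 4.99, or 4.47 with genes at 0 counts set to their bound; camera adjusted p = 2.46e-24, and 0.00665 as the adjusted p with an estimated correlation). Irf7, an interferon regulatory factor, was 178-fold, Rsad2, viperin, at least 159-fold and Apobec3, a cytidine deaminase, at least 104-fold higher. Autophagy genes were split, 24 of 53 higher and 23 lower (camera adjusted p = 0.981; median 0.06, and 0 with RLE), but 32 were higher and 10 lower with library totals (median 0.37). Map1lc3b (2.23-fold), Fam134b (2.8-fold) and Tfeb (3.2-fold) were lower and Tmem41b, an ER scramblase, 3.76-fold higher. Becn1 was higher by 0.2 ± 0.037. Ulk1 was called higher by 0.12 ± 0.05 (adjusted p = 0.0337), a call that ended with RLE and with DESeq2 (0.06 each), with the 4 libraries alone and with summed isoforms (0.12 each), without starved WT replicate 1 (0.05) or replicate 2 (0.06), and without starved KO-labelled replicate 1 (0.07). Txnip differed by 0.8 ± 0.4 (adjusted p = 0.074) and passed without starved WT replicate 2 (1.24), without starved KO-labelled replicate 2 (1.1), without fed WT replicate 1 or replicate 2 (0.8 each), with no filter (0.8) and with library totals (1.11).

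Among lower lists, 70 of 75 ribosomal protein genes were lower and 0 higher in starved KO-labelled cells (median -0.81, and -0.49 with library totals, where 59 were lower and 13 higher; camera adjusted p = 5.26e-21, but adjusted p = 0.317 with an estimated correlation). Contractile genes were lower in 13 of 20 cases and higher in 5 (median -0.59, and -0.27 with library totals; camera adjusted p = 1.76e-07, but adjusted p = 0.0552 with an estimated correlation), and mitosis genes in 29 of 45 with 14 higher (median -0.43, and -0.11 with library totals; camera adjusted p = 0.0217, but 0.0915 with library totals and adjusted p = 0.147 with an estimated correlation), for example Racgap1, of cytokinesis (3.24-fold). Neural and glial markers passed as lower, 5 of 11 with 4 higher (camera adjusted p = 0.00582, but adjusted p = 0.143 with an estimated correlation). Their median was 0.41, or 0 with genes at 0 counts set to their bound, and their mean -0.19. Stmn2, a neuronal microtubule gene, was 501-fold lower. Hox genes did not pass (23 of 36 lower, 7 higher; camera adjusted p = 0.0587) but passed with library totals (0.00437). Hoxc11 was at least 141-fold and Hoxc9 at least 119-fold lower and Hoxd13 400-fold higher. Ehmt2, the H3K9 methyltransferase G9a, was 2.26-fold lower. The H3K9 list did not pass (camera adjusted p = 0.449; median -0.27, mean 0.49, median 0.05 with library totals). Wnt10b, a Wnt ligand gene, had a ratio of 2580 in favour of WT (95% interval 462 to 102000), and Lcn2, lipocalin 2, was 31.8-fold and Mmp3, a matrix protease, 119-fold higher in KO-labelled cells.

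The last comparison asked whether the starvation response differed between the genotypes. The responses of ER chaperone and contractile genes were more positive in KO-labelled cells, and those of mitosis genes more negative. Kdm3a rose 3.21-fold in WT and 1.2-fold in KO-labelled cells (interaction -1.43 ± 0.059). The interaction was -1.13 ± 0.035 for Sqstm1, -0.74 ± 0.045 for Map1lc3b, -1.53 ± 0.077 for Atg14 and 2.94 ± 0.04 for Col1a1, and Bnip3, which rose in WT from 22 ± 0.32 to 61.9 ± 0.39 CPM, fell in KO-labelled cells from 130 ± 1.1 to 72.9 ± 0.66 CPM (-2.33 ± 0.062). In all, 4923 genes had a more positive and 4377 a more negative response in KO-labelled cells. With library totals these were 6306 and 3099 (52.9% of calls positive with TMM, 67% with totals, a median shift of 0.2, and 8 calls turned).

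Of 53 autophagy genes 29 had a more negative and 11 a more positive response (median -0.21, and -0.01 with library totals, where 20 were negative and 19 positive; camera adjusted p = 0.0117, but 0.059 with library totals and adjusted p = 0.107 with an estimated correlation). Becn1 differed by -0.06 ± 0.054 (adjusted p = 0.382), with calls of -0.15 under RLE and DESeq2, of -0.2 and -0.17 without starved WT replicate 1 and replicate 2, and of the opposite sign, 0.14, with library totals. Ulk1 was called at -0.17 ± 0.069 (adjusted p = 0.0412), a call that ended without fed WT replicate 2 (-0.12), without fed KO-labelled replicate 1 (-0.15) or replicate 2 (-0.18), without starved KO-labelled replicate 2 (-0.11), with summed isoforms (-0.17) and with library totals (0.03, adjusted p = 0.689). The ER list was more positive in 35 of 41 genes (36 adjusted over the list alone) and more negative in 3 (median 0.57; camera adjusted p = 1.15e-14, and 0.0103 as the adjusted p with an estimated correlation), for example Pdia4 (1.27 ± 0.035), Ssr1 (1.61 ± 0.045) and Pdia6 (1.17 ± 0.035). Contractile genes were more positive in 14 of 20 and more negative in 4 (median 1.08, and 1.28 with library totals; camera adjusted p = 1.06e-09, and 0.0377 as the adjusted p with an estimated correlation), among them Myl9, a myosin light chain (3.31 ± 0.063), and Acta2 (2.38 ± 0.035). Collagen and matrix genes were more positive in 26 of 43 and more negative in 9 (camera adjusted p = 0.000185, but adjusted p = 0.467 with an estimated correlation). Mitosis genes were more negative in 31 of 45 and more positive in 7 (median -0.43, and -0.23 with library totals; camera adjusted p = 3.75e-07, and 0.0291 as the adjusted p with an estimated correlation), among them Tpx2 (-1.09 ± 0.043) and Prc1 (-1.22 ± 0.053), which act at the spindle.

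Glycolysis genes were more negative in 20 of 25 and more positive in 4 (median -0.5, and -0.29 with library totals; camera adjusted p = 1.49e-05, but adjusted p = 0.143 with an estimated correlation), with Ldha at -1.13 ± 0.035 and Pfkl, a phosphofructokinase, at -1.38 ± 0.05. Hypoxia genes were more negative in 17 of 27 and more positive in 6 (median -0.74, camera adjusted p = 0.00172, but adjusted p = 0.0926 with an estimated correlation). Interferon-stimulated genes were more negative in 24 of 43, such as Rtp4 (-5.35 ± 0.14), and more positive in 1. Their camera adjusted p was 0.00578, but the adjusted p = 0.0965 with an estimated correlation. Their median level in WT was only 0.741 CPM fed and 0.213 CPM starved, with 4 of 43 at 0 in starved WT. This limits how well their WT response was measured. For Oas2 and Iigp1, with at most 3 counts in a WT group, the interaction call (adjusted p = 0.00265 and 0.00188) was lost without starved WT replicate 1. The fitted interaction then went from -5.43 to -0.94 for Oas2 but only from -5.26 to -4.83 for Iigp1. Of 28 p53 targets 17 were more positive and 7 more negative (camera adjusted p = 0.022, but adjusted p = 0.144 with an estimated correlation). Phlda3 stood at 2.33 ± 0.075 and Mdm2, the p53 ligase, at -1.28 ± 0.05. Sterol genes were more positive in 15 of 34 and more negative in 10 (camera adjusted p = 0.0191, but adjusted p = 0.249 with an estimated correlation), with Scd2 at 2.75 ± 0.041. Immediate-early genes were more negative in 13 of 26 and more positive in 6 (7 adjusted over the list alone; camera adjusted p = 0.0191, but adjusted p = 0.143 with an estimated correlation). Their median of -0.25 became -0.05 with library totals, where 10 were more negative and 9 more positive. Ribosomal protein genes were more negative in 66 of 75 (median -0.25, and -0.05 with library totals, where 17 were negative and 9 positive; camera adjusted p = 0.000194, but 0.0539 with library totals and adjusted p = 0.686 with an estimated correlation). The ATF4 list did not pass (camera adjusted p = 0.143) but did with library totals (0.0134), and the lysosome list did not pass (camera adjusted p = 0.116; median -0.25, mean 0, median -0.05 with library totals) but did with RLE (0.0484).

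**Figure D3:**
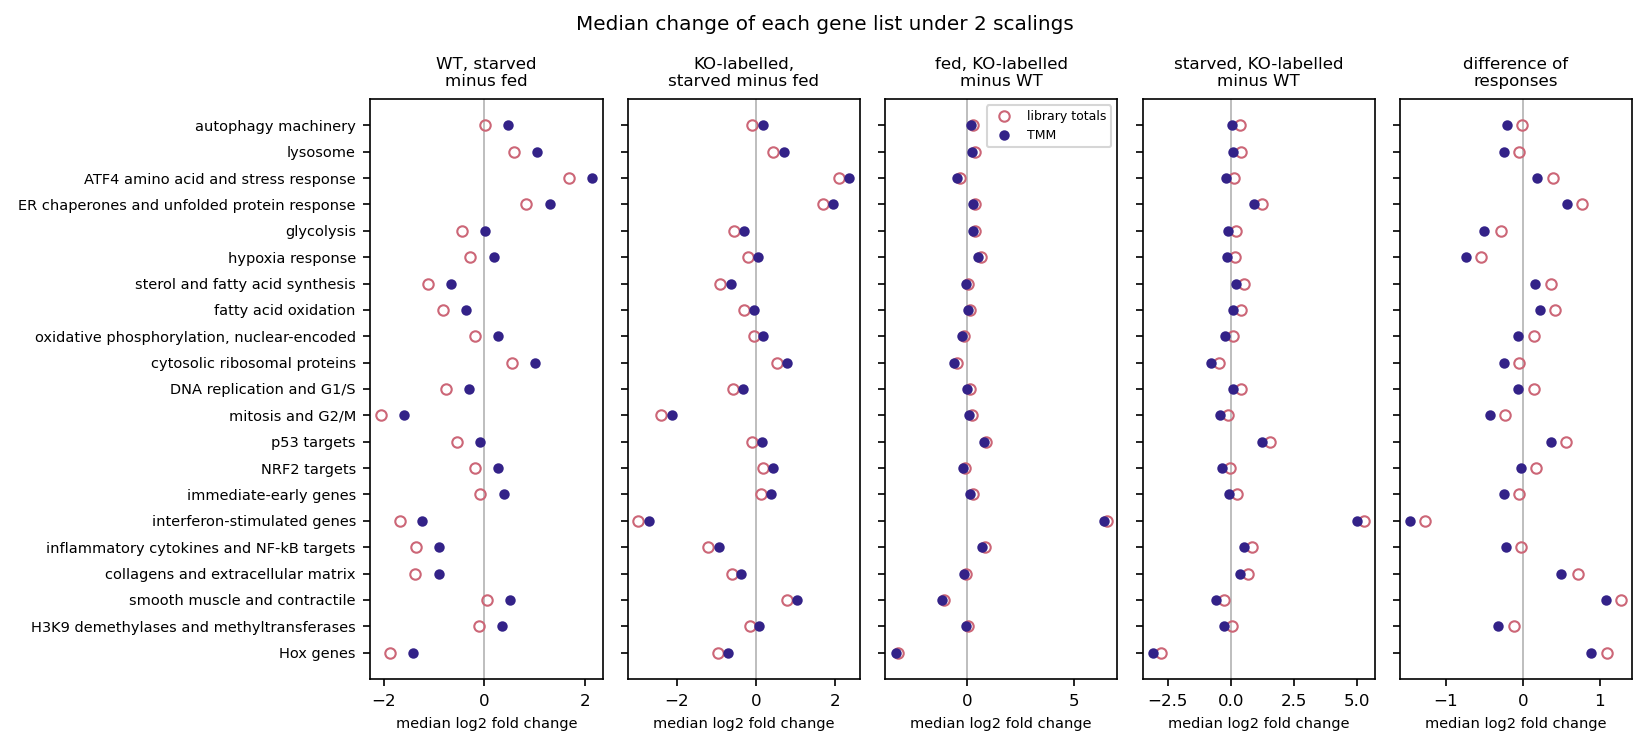
Median log2 fold change (horizontal axes) of each gene list with at least 18 tested members in the 5 comparisons, with TMM scaling (filled) and library totals (hollow). The 43 interferon-stimulated genes have medians of 6.4 and 4.99 in the fed and starved comparisons of KO-labelled with WT libraries, and hollow points lie on the other side of 0 in at least 1 panel for the autophagy, ATF4, glycolysis, hypoxia, sterol, oxidative phosphorylation, DNA replication, p53, NRF2, immediate-early and H3K9 lists.

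Across the 14418 genes, the starvation responses of WT and KO-labelled cells correlated at Pearson r = 0.63 and Spearman rho = 0.68 (covariance 1.75). The comparisons share no library, and genes are not independent replicates. Both rose for 4063 genes (2086 for independent lists), both fell for 4353 (2606), and 1383 were called in opposite directions. The differences between the labels when fed and when starved correlated at r = 0.7 and rho = 0.56 (covariance 2.56), with 3433 genes higher in both (2085 for independent lists), 3593 lower in both (2165) and 1952 in opposite directions. The KO-labelled response had a slope of 0.58 to 0.59 on the WT response over 4 splits. It was weighted by one pair of WT libraries and measured against the other pair. With the roles exchanged, the WT response had a slope of 0.81 to 0.82 on the KO-labelled response. The slopes are not inverse to each other, so each mixes the size of a response with the agreement of the responses. They give no relative size.

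Markers of other cell types that a MEF culture can hold were read as well. Of 19 macrophage and blood cell markers in the table, 10 had 0 counts in fed KO-labelled libraries, and the pan-leukocyte gene Ptprc had 0 counts in each library. Cd68, a macrophage marker, rose in KO-labelled cells from 3.49 ± 0.19 to 40.8 ± 0.15 CPM, alongside the falling interferon-stimulated genes, and Csf1r, a macrophage receptor, from 0.418 ± 0.028 to 6.23 ± 0.28 CPM. Of 6 tested members, 1 rose and 3 fell in WT, and 3 rose and 2 fell in KO-labelled cells. Between starved cells 5 were higher and 0 lower in the KO-labelled libraries, and 4 had a more positive and 0 a more negative response there. The list passed in no comparison (lowest camera adjusted p = 0.2). Endothelial markers (9 tested, lowest camera adjusted p = 0.349) did not pass, though Kdr, an endothelial receptor, rose in starved WT from 2.06 ± 0.2 to 53.8 ± 1.5 CPM. Neither did epithelial (8 tested, lowest 0.462), skeletal muscle (8 tested, lowest 0.756), cartilage and bone (15 tested, lowest 0.185) or adipocyte markers (9 tested, lowest 0.182). Neural and glial markers passed as lower in fed KO-labelled libraries, 7 of 11 with 4 higher (camera adjusted p = 6.13e-05, but adjusted p = 0.0669 with an estimated correlation): Stmn2 was 630-fold and Nes, nestin, 6.53-fold lower and Fabp7, of glia, 66-fold higher. In that comparison, fatty acid oxidation (camera adjusted p = 0.772; median 0.04, mean -0.28, median 0.16 with library totals), H3K9 (0.823; median -0.05, mean 0.28, median 0.06 with library totals), NRF2 (0.981) and immediate-early genes (0.516; median 0.16, mean -0.04, median 0.28 with library totals) did not pass.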

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

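The tests weighed in the last 3 paragraphs of this part were chosen after the results were seen. The interaction test was planned. The results below had a response to starvation that differed between KO-labelled and WT cells by the interaction test. In all, 4923 genes had a more positive and 4377 a more negative response in KO-labelled cells. The test called 64.5% of the 14418 tested genes. It also called 114 of the 124 genes taken from the text on the starvation responses, so a call sets few genes apart. By list, the camera adjusted p of the interaction was 1.15e-14 for ER chaperone, 1.06e-09 for contractile and 0.000185 for collagen and matrix genes, 0.0191 for sterol and 0.022 for p53 target genes, each in the positive direction. In the negative direction it was 3.75e-07 for mitosis, 1.49e-05 for glycolysis, 0.000194 for ribosomal protein, 0.00172 for hypoxia, 0.00578 for interferon-stimulated, 0.0117 for autophagy and 0.0191 for immediate-early genes. With an estimated correlation only the ER, contractile and mitosis lists passed among these 12. Among the others the estimate was below the preset 0.01 for hypoxia (-0.031), interferon-stimulated (-0.01), immediate-early (-0.006), autophagy (-0.003) and p53 target genes (0). It was above it for sterol (0.032), glycolysis (0.075), collagen and matrix (0.27) and ribosomal protein genes (0.605).

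With library totals the median interaction of all genes moved by 0.2, more than the size of the negative values of Ulk1, Hspa5 and Rpl3 below. Their sign therefore rests on TMM scaling. Interaction log2 fold changes follow in parentheses, positive where the response was more positive in KO-labelled cells. Among autophagy and lysosome genes they were, below 0, Sqstm1 (-1.13), Map1lc3b (-0.74), Fam134b (-1.45), Atg14 (-1.53), Atg3 (-0.8), Tfeb (-1.16), Ulk1 (-0.17), Bnip3 (-2.33), Atp6v1c1 (-0.76), Ctsa (-0.88), Lamp1 (-0.82) and Neu1 (-0.54) and, above 0, Atg13 (0.48) and Atp6v1b2 (0.7). Stress and ER genes had negative values for Atf3 (-2.81), Gadd45a (-1), Ppp1r15a (-0.86), Chac1 (-1.04), Hspa5 (-0.12), Hmox1 (-1.94) and Gclc (-1.57) and positive values for Ddit3 (0.28), Slc3a2 (0.63), Slc7a3 (3.07), Hyou1 (0.96), Creld2 (1.17), Pdia4 (1.27), Ssr1 (1.61), Pdia6 (1.17) and Adm2 (1.42). The demethylase and methyltransferase genes were Kdm3a (-1.43), Kdm4b (-0.97), Jmjd1c (-0.86), Kdm4c (-0.86), Ehmt2 (-0.81) and Kdm4a (0.36). For glucose metabolism and hypoxia the values were Ldha (-1.13), Slc16a3 (-0.54), Tpi1 (-0.47), Pfkl (-1.38), Aldoa (-0.78), Hk2 (-0.85), Arrdc4 (-3.25), Ndrg1 (-1), Ero1l (-0.57), Vegfa (-1.46) and Plod2 (-1.39) and, in the other direction, Ldhb (3.03) and Pdk4 (1.11). Lipid genes stood at Scd2 (2.75), Idi1 (1.1) and Acadm (0.59).

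Proliferation genes were Kif20a (-0.41), Top2a (-0.36), Plk1 (-1.53), Racgap1 (-1.13), Tpx2 (-1.09), Prc1 (-1.22), Mcm2 (-0.67) and Hist1h1c (-1.92), with Mki67 (0.38) and Tk1 (1.06) in the other direction. Matrix and stromal genes were mostly positive, Col1a1 (2.94), Col1a2 (1.19), Col3a1 (1.81), Cd248 (3.32), Medag (1.47) and Gas1 (1.64), with Col8a1 (-2.59) as an exception, and so were the contractile genes Tagln (1.02), Fhl1 (0.44), Tpm1 (1.32), Acta2 (2.38) and Myl9 (3.31). Immune genes had negative values for Irgm1 (-1.21), Rtp4 (-5.35), Oas3 (-5.15), Serpina3g (-1.79), Ptgs2 (-2.1), Ccl2 (-0.36) and Cxcl12 (-0.91) and positive ones for Cxcl5 (1.05), Il1rn (3.77), Cd68 (2.73) and Csf1r (3.43). Oas3 had only 9 counts in its lowest group. The p53 targets were Phlda3 (2.33) and Mdm2 (-1.28) and the ribosomal protein genes Rpl3 (-0.12), Rpl10a (-0.21) and Rpl7a (-0.37). Other genes below 0 were Fam110c (-3.74), Plcxd2 (-2.77), Angpt1 (-1.86), Rgs4 (-3.39), Kdr (-4) and Hoxa10 (-1.02). Those above were Car6 (2.17), Ddit4l (6.05), Avil (4.55), Hey2 (4.5), Hid1 (4.12), Atp2a3 (3.14), Kcnh2 (5.03), Zmat1 (4.83), Jrk (4.82) and Xist (0.51). The call of Xist was close to the threshold (0.51 ± 0.22, adjusted p of the interaction test 0.0494) and rests on low WT levels, with 81 counts in its lowest group. Car6 had 16 counts in its lowest group. For 8 genes with a group at 6 counts or fewer no size is given in this paragraph. The adjusted p of the interaction is given in parentheses: Gata4 (0.00792), Steap4 (0.0403), Adamts4 (1.04e-05), Skida1 (8.26e-05), Sspo (5.08e-05), Apobec3 (0.00379), Iigp1 (0.00188) and Oas2 (0.00265).

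Kdm3a was not lower in the fed libraries labelled KO. An exchange of the fed labels is argued against by Xist, whose lowest level in these libraries was 869 CPM, near that of the starved KO-labelled and far from that of the starved WT libraries. A deletion that leaves a counted transcript cannot be told apart from an intact gene: the lowest Kdm3a count in a KO-labelled library was 2788, and counts per exon were not used here. The lower Kdm3a level of KO-labelled cells after starvation leaves both open.

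Most genes differed between fed KO-labelled and fed WT libraries. The called share was 74.2% of autosomal genes and also 74.2% of genes on chromosomes other than that of Kdm3a. These shares follow from the share of all genes, so dosage of the X and Y chromosomes and variants near Kdm3a, whose effects can reach other chromosomes, cannot be told apart from genotype. Cultures that came from another embryo, sex or body position cannot be told apart from genotype, because each label stands for 1 sex. 86.1% of tested Hox genes were called. The loss of Kdm3a, which the design names, stays open as a candidate explanation alongside these.

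Interferon-stimulated genes were higher in the libraries labelled KO, fed and starved. Abundant blood cells in the fed cultures are argued against by 0 counts of Ptprc in each library. The median of their markers was 0 CPM in fed KO-labelled libraries, where the interferon-stimulated genes had a median of 88.528 CPM. As the marker median was 0 CPM in each group, it cannot exclude a small share of blood cells. Cd14 stood at 16.1 CPM in fed WT and 17.4 CPM in fed KO-labelled libraries, and Lyz2 had 3 and 57 counts. Of 6 tested markers 2 were higher and 2 lower in fed KO-labelled libraries. For starved cells the presence of blood cells was not weighed. The marker median was 0 CPM in starved KO-labelled libraries too, but Cd68 stood at 40.8 CPM there and 3.7 CPM in starved WT, and Csf1r at 6.23 and 1.32 CPM. Scaling is argued against by median differences of 6.52 between fed and 5.29 between starved cells with library totals. An interferon response of these cultures that is unrelated to the genotype cannot be told apart from an effect of the knockout, since Isg15 was at 54.2 CPM or more in each KO-labelled and below 1 CPM in each WT library. Whether loss of Kdm3a raises these genes therefore stays a hypothesis that other clones or embryos could test.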

How the results depend on the processing

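Library totals, summed isoforms and counts without X- and Y-linked genes were chosen after seeing the data. The rest were planned. Of 10 counts of genes, 9 stayed within 1.5 times under each alternative run, and the rises in WT fell to 3397 with library totals, whose constructed shift of all genes lowers them. Of 140 list tests 91 kept their side of the threshold under each alternative run, 39 lost it somewhere and 10 passed somewhere. Left-out libraries, a mean CPM of at least 5 and summed isoforms were run for the 5 autophagy tests alone. Of 307 values of named genes 298 kept direction and side. For the autophagy list the camera adjusted p was, with an estimated correlation, 0.0669 in WT starvation, 0.143 between fed cells and 0.107 for the interaction, which stood at 0.059 with library totals. For starvation of KO-labelled cells it was 0.0491 with summed isoforms and 0.0491 to 0.065 with each library left out. The cause was not tested. The response ratio was 0.572 with a prior count of 0.5, 0.595 with one of 8 and 0.645 with a mean CPM of at least 5, which also gave correlations of 0.75 for the starvation responses and 0.79 for the genotype effects, over fewer genes. Signs of single named genes were compared for these 307 values alone. Map1lc3b in starved KO-labelled cells did not keep its sign, with 0 at a mean CPM of at least 5 and -0.15 at library totals. With library totals the interactions of Becn1 (0.14) and Ulk1 (0.03, adjusted p = 0.689) did not keep theirs. The cause was not tested.

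The replicate numbers share only a number: replicate differences correlated at -0.09 to 0.01 between groups. A replicate block kept 98.1 to 98.7% of calls by comparison and moved no count by over 1.5 times. 11 list tests no longer passed and 4 newly passed: oxidative phosphorylation in WT starvation (camera adjusted p = 0.0152), Hox genes between starved cells (0.0152), and ER (0.00819) and hypoxia genes (0.0209) between fed cells. Lost in WT starvation were hypoxia (0.34), NRF2 (0.149), immediate-early (0.0648), contractile (0.063) and collagen genes (0.0555), and in KO-labelled starvation Hox genes (0.0555). Between fed cells collagen genes (0.367) and neural markers (0.0684) were lost, and between starved cells neural markers (0.455). In the interaction sterol (0.205) and immediate-early genes (0.173) were lost. A library left out leaves 1 in its group, which is assumed to vary like the others. A fit of 4 libraries alone gives no interaction value. With 3 counts as the floor, at 38407526 to 53602297 counts per library, levels below 0.049 to 0.092 CPM were not resolved.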

Other observations

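The 3 gene groups in this part were chosen after the results were seen. No list test was run on them, so the counts below are of single genes and say nothing about the groups against other genes. Of all tested genes 81.6% were called in WT starvation, 79.7% in starvation of KO-labelled cells, 74.4% between fed cells and 64.5% in the interaction. Of 14 circadian clock genes, 9 rose and 5 fell in starved WT, 7 rose and 5 fell in starved KO-labelled cells, and 10 had a more negative and 1 a more positive response in KO-labelled cells. Nr1d1, a repressor of the clock (REV-ERB alpha), rose in WT from 49.3 ± 0.41 to 277 ± 5.5 CPM and in KO-labelled cells from 67.4 ± 1.3 to 72.5 ± 0.046 CPM (interaction -2.38 ± 0.054). Its relative Nr1d2 rose by 1.93 ± 0.036 and by 0.31 ± 0.036 on the log2 scale. Bhlhe40, another repressor, rose by 1.27 ± 0.05 in WT and differed by 0.05 ± 0.05 in KO-labelled cells (adjusted p = 0.381). Arntl, the activator BMAL1, rose in both, by 2.23 ± 0.085 and 1.42 ± 0.075, as did the repressor Cry1, by 2.08 ± 0.075 and 2.23 ± 0.078. Per3, a period gene, fell in both. No group was kept fed for 12 h. These changes of clock genes therefore cannot be separated from the 12 h of time or the change of medium.

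Of 19 tested imprinted genes 4 were higher and 15 lower in fed KO-labelled than in fed WT libraries, where 74.4% of all genes were called. H19, a maternally expressed RNA, stood at 31.7 ± 1.4 CPM in WT and 1.54 ± 0.13 CPM in KO-labelled cells, Igf2, a growth factor, at 13.1 ± 0.71 and 0.168 ± 0.1 CPM, and Peg10, a paternally expressed gene, at 296 ± 9.3 and 17.8 ± 1.5 CPM. Plagl1, a zinc finger gene, was higher (4.28 ± 0.35 and 44.2 ± 0.014 CPM), and so was Dio3, a deiodinase (1.84 ± 0.043 and 13.6 ± 0.63 CPM). Of 24 tested transcription factors of limb and body position, 7 were higher and 16 lower in the same comparison. Pitx1, of the hindlimb, stood at 180 ± 3.1 and 27.2 ± 1.8 CPM, Tbx3 at 18 ± 0.7 and 0.972 ± 0.11 CPM and Shox2 at 43.3 ± 1.8 and 1.55 ± 0.055 CPM. Tbx4, also of the hindlimb, was higher (19.5 ± 3.2 and 49.9 ± 0.65 CPM). Tbx5, of the forelimb, was at least 32.7-fold higher, and Hand2, of the posterior limb, at least 62.8-fold lower. The 4 further columns of the deposited table match no described library and were not used here.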
